A study of Homo sapiens with 8 samples.

How the data were processed

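RNA of 8 MCF7 samples was measured, with input and polysome RNA after transfection of tRF-HIS or tRF-SC and 2 libraries in each of the 4 groups. Per the labels' protocols, total RNA was extracted from lysate or pooled polysome fractions, poly(A)+ RNA was selected from 20 µg, and 400 ng of it was fragmented to about 300 nt and built into libraries by MSR-seq, a protocol based on adapter ligation. The deposited table holds RSEM expected counts per gene, per the file headers, with 1 column per library and no scaling between libraries. The submitters' processing notes name the hg38 build and SAMtools. The aligner, the software versions, the annotation release, the strand setting and any use of molecular identifiers are not given in the sources used here. It is therefore not known whether overlapping genes were told apart by strand or whether duplicate reads were removed. Of the expected counts of 1 or more, 17.8% were not whole, so values were rounded before testing. Library totals ran from 282355 to 539327 in polysome RNA and from 2185378 to 5531415 in input RNA, and 3 counts in the shallowest library equal 10.6 CPM. Floors and counting intervals cover counting error only.

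The table has 61533 genes as versioned Ensembl IDs, of which 61369 matched the name table and 58356 the GENCODE 29 annotation. Genes were kept by edgeR's filterByExpr on the 4 groups with a minimum count of 10, which left 10131. Library sizes were scaled by TMM, whose factors were 0.878 to 0.95 in input and 1.077 to 1.131 in polysome libraries. The quasi-likelihood test of edgeR 4.0.16 (estimateDisp, glmQLFit with robust estimation, glmQLFTest; R 4.3.3) was fitted to all 8 libraries with a mean per group, which leaves 4 residual degrees of freedom. Contrasts gave tRF-HIS against tRF-SC in input RNA and in polysome RNA, polysome against input RNA averaged over both transfections, and the difference between transfections in the polysome-to-input ratio. Adjusted p values are Benjamini-Hochberg values over all genes of a comparison, with a threshold of 0.05 and no fold minimum. CPM values (edgeR cpm) use the TMM-scaled library sizes and are given as mean ± SD. Standard errors of log2 fold changes are the fold change divided by the square root of the test's F statistic. All tests are two-sided.

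The comparisons, tests, gene lists, named-gene rule and first set of alternative settings were set before the data were examined. The text names, per comparison, up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold with a mean of at least 5 CPM, an official symbol and no overlap between the libraries of the groups. Where fewer than 5 genes passed in a direction, the 5 with the smallest p under the same CPM and symbol conditions are named as not passing. The 4 members with the smallest p of each list past the threshold are named too. The 14 genes QTRT1, QTRT2, HARS1, HARS2, ANG, DICER1, MYC, CCND1, MKI67, CDKN1A, ESR1, ATF4, ACTB and GAPDH are named whatever their result, and ANG was not among the tested genes. The 30 gene lists cover tRNA biology, translation, noncoding RNA, mitochondria, cell cycle, hormone, stress and immune responses, metabolism and cell type markers, and 984 of their 986 entries matched a symbol. The 28 lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01.

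Replicate pairs were compared before averaging, and their chi-square per degree of freedom was 6.18 to 13.9, so no library looked like a second copy of another. Transcript GC content, coding sequences and coordinates came from GENCODE 29, on hg38. For genes named in the text and genes called between polysome and input RNA, the share of transcript words of 50 nt found in other genes was counted. A gene with at least 50% of its words elsewhere was tested again with its counts summed with those of every gene that holds at least 10% of them.

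The steps were tested on simulated counts drawn from the real means and library sizes, with the same common dispersion for all genes of a fraction. Of the 10131 genes, 200 were changed, in 3 draws per comparison. A spread that differs from gene to gene was not simulated, and filterByExpr was not run on the simulated counts. The shares below hold for that setting only. For tRF-HIS against tRF-SC in input RNA, 0, 10 and 96.5% of genes changed 2-, 4- and 16-fold were recovered, with 0 false among 211 calls. In polysome RNA the shares were 1, 11.9 and 58.6%, with 39 false among 181 calls, and 11.19% of unchanged genes had an unadjusted p under 0.05. For polysome against input RNA they were 5, 48.3 and 89.9%, with 16 false among 301 calls, and for the difference between transfections 0, 0 and 8.1%, with 0 false among 16 calls. In input RNA, 0.51% of unchanged genes had an unadjusted p under 0.05. In a fit to the compared libraries alone, 21.4, 90 and 99.5% were recovered in input RNA (13 false among 434 calls) and 0, 2 and 35.9% in polysome RNA (5 false among 80 calls).

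Settings chosen in advance were median-ratio size factors, library totals, no count filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, a fit to the compared libraries alone, the replicate number as a block, leaving out mitochondrially encoded genes, leaving out each library in turn, and for lists an estimated correlation and fry. Added after the data were seen were a GC correction (loess of each library's log2 CPM deviation on GC content), that correction with the block, limma voom with a spread per group, the summed counts above, and the interferon list without tRF-HIS replicate 2 in both fractions. For tRF-HIS against tRF-SC within a fraction, the block was the replicate number. For the comparisons over both fractions, it was each combination of transfection and replicate number. Fits without a library, or to the compared libraries alone, filtered the genes anew. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. All 8 columns of the deposited table were used.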

Results

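MCF7 cells, an epithelial breast cancer line that carries the estrogen receptor, were grown in dialyzed serum with 1 µM queuine. Queuine is the base from which cells make the queuosine modification of certain tRNAs. Per the labels, the medium of every sample also held the hormones estradiol (10 nM) and insulin (10 µg/mL). The design text gives at least 48 h of queuine and the growth protocol at least 24 h. The cells were then transfected with tRF-HIS, a fragment of histidyl tRNA, or with tRF-SC, the other fragment of the design, whose name the labels do not spell out. Poly(A)-selected RNA was sequenced from whole lysate, called input RNA, and from pooled polysome fractions, which hold the mRNAs bound by several ribosomes. Each of the 4 groups had 2 libraries. Nothing in the labels says that these came from separate cultures, so every p-value measures only the spread between these samples, which may be technical.

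The 2 tRF-SC input libraries held 2185378 and 3790859 expected counts, and the tRF-HIS input libraries held 5531415 and 3513373. The polysome libraries were shallower, with 370854 and 539327 expected counts after tRF-SC and 375076 and 282355 after tRF-HIS. Pairwise Pearson correlations of log2 CPM, the counts scaled to library size, over the 10131 tested genes lay between 0.926 and 0.971 among input libraries and between 0.689 and 0.746 among polysome libraries. The biological coefficient of variation was 23.5% in input RNA and 58.3% in polysome RNA. All 8 libraries were also thinned to the 282357 rounded counts of the shallowest. Replicates then correlated at 0.894 (tRF-SC) and 0.906 (tRF-HIS) in input RNA and at 0.828 and 0.796 in polysome RNA. These thinned values compare only with each other, since polysome replicates correlated lower at full depth, at 0.741 and 0.694. Mitochondrially encoded mRNAs took 1.15 to 2.31% of counts in input libraries and 0.316 to 0.745% in polysome libraries.

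The first comparison asked whether the transfected fragment changed mRNA levels in the cells. Genes of the interferon and RNA-sensing response were higher as a group in tRF-HIS than in tRF-SC input RNA, with a median log2 fold change of 0.32 and 19 of 25 measured members above 0 (camera, adjusted p = 0.000234). With an estimated inter-gene correlation, the p of this list was 0.0526 and its adjusted p = 0.834. IFI6, an interferon-induced protein, measured 242 ± 68.5 CPM after tRF-SC and 483 ± 332 CPM after tRF-HIS (mean ± SD, n = 2 each), a log2 fold change of 1.00 ± 0.41 (SE). IFI27 measured 46.4 ± 10.5 and 106 ± 92.4 CPM, a log2 fold change of 1.18 ± 0.55. STAT1, the transcription factor that interferon receptors activate, had a log2 fold change of 0.65 ± 0.53, and OAS1, a sensor of double-stranded RNA, one of 1.40 ± 1.10. None of the 25 members passed the test on its own, over all genes or adjusted over the list alone. Most of the list's height came from tRF-HIS replicate 2, in which 16 of the 25 members had their highest value of the 4 input libraries. Unnamed genes resembling ribosomal RNA took 10.1% of the counts of that library, against 6.58 to 8.25% in the other input libraries. Protein-coding genes took 85.4%, against 87.9 to 88.9%. Without tRF-HIS replicate 2 the list's median was 0.011, and without tRF-SC replicate 2 it was 0.30. These fits filtered the genes anew and held 19 members of the list. With tRF-HIS replicate 2 left out of both fractions, the list had 25 members and a median of -0.0038. Over the alternative settings of camera, the adjusted p of this list ran from 2.38e-08 to 0.913, and in fry it was 0.979.

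**Figure D1:**
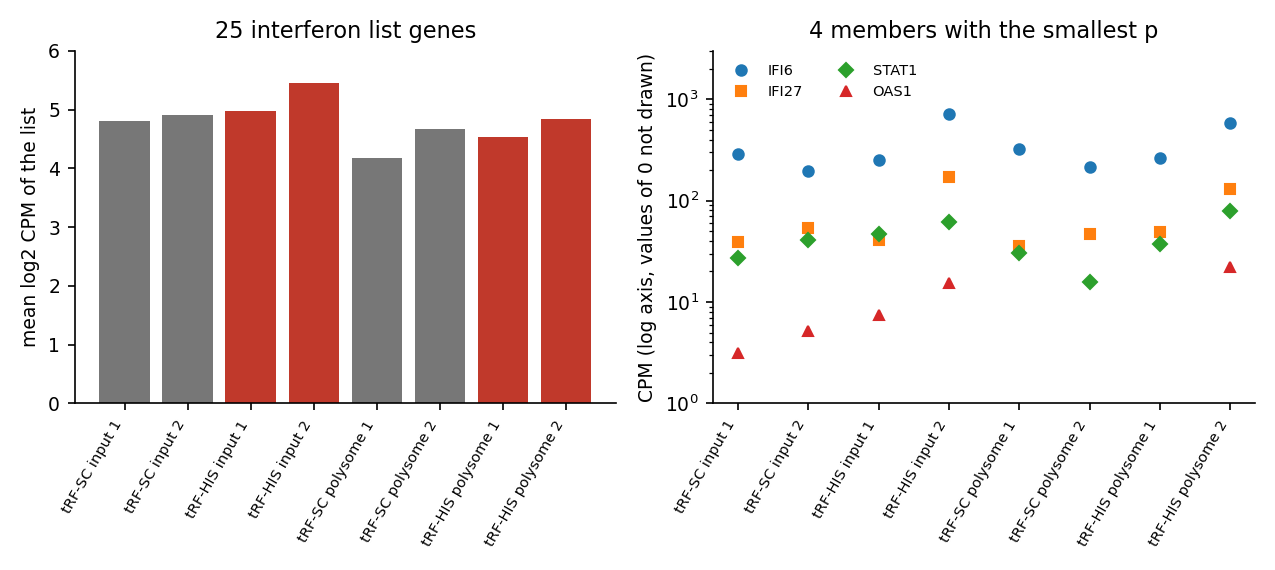
Left, mean log2 CPM of the 25 measured interferon list genes in each of the 8 libraries (bars, tRF-SC in grey and tRF-HIS in red). Right, CPM on a log axis of the 4 members with the smallest p. The list mean was 4.81 and 4.91 in the tRF-SC input libraries and 4.97 and 5.44 in the tRF-HIS ones.

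No single gene passed between tRF-HIS and tRF-SC input RNA in edgeR's quasi-likelihood test (0 of 10131 genes). At an unadjusted p under 0.05 there were 27 genes, where 507 would be expected by chance, so this fit was strict. In simulated data it recovered 10% of genes changed 4-fold, against 90% in a fit to the input libraries alone. The 0 is therefore no sign that mRNA levels were unchanged. DESeq2 also called 0 genes, with 31 at an unadjusted p under 0.05. With only the 4 input libraries in the fit, 1 gene was called higher and 3 lower, and limma voom with a spread for each group called 4 lower. The 10 genes with the smallest p did not pass (adjusted p = 1). C1orf122 measured 186 ± 43.0 CPM after tRF-SC and 109 ± 3.57 CPM after tRF-HIS, a log2 fold change of -0.76 ± 0.30. SNRNP70, a protein of the U1 spliceosomal particle, had -0.74 ± 0.31, and PTMS, parathymosin, -0.69 ± 0.26. Without single libraries, SNRNP70 ran from -1.04 to -0.25 and PTMS from -0.99 to -0.21. SLX1A had -1.79 ± 0.58 on its own and -0.26 ± 0.37 when its counts were summed with the genes that hold the same sequence, SLX1B and the SULT1A3 and SULT1A4 readthrough genes. RPL36A-HNRNPH2 had -2.73 ± 1.06 alone and 0.10 ± 0.24 summed, and ABCF2-H2BK1 3.56 ± 1.44 alone and 0.29 ± 0.42 summed with the genes it reads through. MSL3P1 had 3 counts after tRF-SC and 111 after tRF-HIS, a ratio of 23.8 (exact 95% counting interval 7.93 to 117), and a summed log2 fold change of 0.36 ± 0.68. PWP2 had 2 and 39 counts, a ratio of 12.5 (3.24 to 107), and a summed value of -0.018 ± 0.53.

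Genes of the queuosine pathway and of proliferation did not differ past the threshold in input RNA. The list of the queuosine pathway and the synthetases of its tRNAs had a median log2 fold change of 0.11. Of its members, 12 of 13 lay above 0 (camera, adjusted p = 0.427). QTRT1, the catalytic subunit of the enzyme that inserts queuine, measured 47.0 ± 1.35 CPM after tRF-SC and 48.5 ± 4.33 CPM after tRF-HIS. Its partner QTRT2 had a log2 fold change of 0.27 ± 0.95, and the histidyl-tRNA synthetases HARS1 and HARS2 had 0.12 ± 0.37 and -0.25 ± 0.49. MYC had 0.23 ± 0.37, CCND1 (cyclin D1) -0.085 ± 0.27, MKI67, a marker of cycling cells, -0.11 ± 0.70, and the cell cycle inhibitor CDKN1A -0.018 ± 0.25. DICER1 had 0.55 ± 0.99, ESR1 (the estrogen receptor) 0.46 ± 0.66, ATF4 -0.14 ± 0.25, ACTB 0.066 ± 0.20 and GAPDH -0.11 ± 0.20, and the adjusted p of each gene in this paragraph was 1. The G2 and M phase list had a median log2 fold change of 0.071 over 38 members (adjusted p = 0.373), the S phase list 0.053 over 39 (adjusted p = 0.891) and the G1 and growth-factor list 0.0068 over 26 (adjusted p = 0.896).

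Fold changes in input RNA fell with the GC content of the transcript, with a Spearman rho of -0.45 across 10076 genes, which are not independent replicates. The slope on GC content differed between replicates of the same group. It was 0.34 and -0.15 log2 CPM per 10 points of GC in the tRF-SC input libraries and 0.026 and -0.22 in the tRF-HIS ones.

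**Figure D2:**
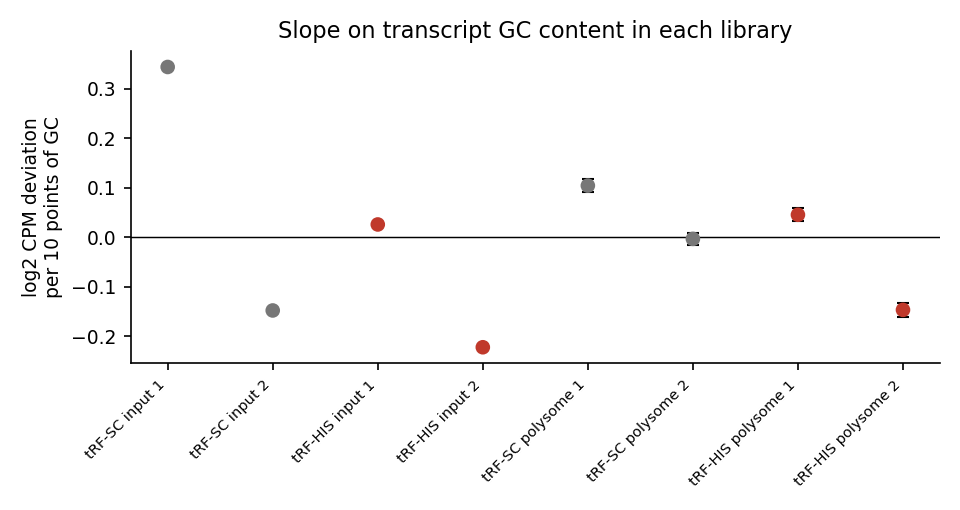
Slope of each library's log2 CPM deviation on transcript GC content, per 10 points of GC (points, tRF-SC in grey and tRF-HIS in red, with standard errors as bars, smaller than the points in the input libraries). The tRF-SC input libraries stood at 0.34 and -0.15, on both sides of the tRF-HIS input library at 0.026.

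In polysome RNA, the question was which mRNAs were more or less abundant on ribosomes after tRF-HIS. U2AF1L5 (ENSG00000275895, hg38 chromosome 21, 6484623 to 6499261), a copy of the splicing factor gene U2AF1, was lower, at 187 ± 3.41 CPM after tRF-SC and 28.2 ± 4.95 CPM after tRF-HIS (mean ± SD, n = 2 each). Its log2 fold change was -2.74 ± 0.46 (SE; adjusted p = 0.0374). Of its transcript words of 50 nt, 94.3% also occur in other genes, and the summed counts of U2AF1L5 and U2AF1 gave a log2 fold change of -0.12 ± 0.30. It did not pass without tRF-SC polysome replicate 2 or without tRF-HIS polysome replicate 1. U2AF1L5 was named after its values were seen, because it was the only gene past the threshold in edgeR's test of the 10131 genes. In simulated data of this fit with 200 changed genes, 39 of 181 calls over 3 draws were false. That share depends on how many genes change, so it is not the chance that the call of U2AF1L5 is false.

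The other genes with the smallest p in polysome RNA did not pass. SLC39A6, a zinc transporter induced by estrogen, measured 84.1 ± 26.2 CPM after tRF-SC and 301 ± 53 CPM after tRF-HIS, a log2 fold change of 1.82 ± 0.39 (adjusted p = 0.102). KDM5C, a histone H3 demethylase, measured 120 ± 37.1 and 13.4 ± 5.49 CPM, a log2 fold change of -3.12 ± 0.58 (adjusted p = 0.0851). S100A8, a calcium-binding protein, measured 87.3 ± 2.08 and 10.0 ± 3.72 CPM (adjusted p = 0.102). HAUS4, a subunit of the spindle complex augmin, measured 5.61 ± 4.37 and 69.2 ± 14.1 CPM, and PPP2R5D, a regulatory subunit of protein phosphatase 2A, 5.92 ± 5.91 and 70.0 ± 8.40 CPM (adjusted p = 0.114 for both). ADCY9, an adenylate cyclase, had 1 count after tRF-SC and 37 after tRF-HIS, a ratio of 49.8 (exact 95% counting interval 8.40 to 2019; adjusted p = 0.0851). GAS8 had 58 and 2 counts, a ratio of 21.5 in the other direction (5.70 to 182; adjusted p = 0.102). STK32C was listed at 0 in both tRF-HIS polysome libraries, at least 9.61-fold lower than after tRF-SC with a floor of 3 counts over the group (adjusted p = 0.114). RBM14-RBM4 was likewise at least 8.87-fold lower alone (adjusted p = 0.102), with a summed log2 fold change of -0.35 ± 0.27, and RPL17P7 had 2 counts after tRF-SC and 37 after tRF-HIS alone (adjusted p = 0.102) and a summed value of 0.21 ± 0.27.

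ESR1 measured 13 ± 18.5 CPM in tRF-SC and 62.5 ± 1.19 CPM in tRF-HIS polysome RNA. Its log2 fold change of 2.12 ± 0.81 did not pass (adjusted p = 0.329). The tRF-SC polysome libraries held 0 and 15 of its counts, and the value ran from 1.24 to 10.0 without single libraries. In the estrogen response list, 22 of 36 members lay above 0, with a median of 0.13 (adjusted p = 0.620). None of its members passed over all genes, and 2 were higher when adjusted over the list alone. The interferon list had a median of 0.34 in polysome RNA, with 16 of 25 members above 0 (adjusted p = 0.620). Without tRF-HIS polysome replicate 2 the list's median was -0.062, and without tRF-SC polysome replicate 2 it was 0.93. These fits filtered the genes anew and held 30 members of the list. With tRF-HIS replicate 2 left out of both fractions, the list had 25 members and a median of -0.07. In the fit to all libraries, 0 of the 25 members passed over all genes and 1 was higher when adjusted over the list alone. Mitochondrially encoded mRNAs had a median of -0.62 over 12 members (adjusted p = 0.0934, and p = 0.352 with an estimated correlation), and 0 of the 28 lists passed. In camera, the mitochondrial list passed as lower with the replicate block (adjusted p = 0.0257) and with the GC correction (adjusted p = 0.0117). QTRT1 had a log2 fold change of -0.84 ± 0.68, QTRT2 -0.26 ± 1.35, HARS1 -0.15 ± 0.42, HARS2 -0.052 ± 0.56, MYC -0.018 ± 0.41, CCND1 -0.19 ± 0.29, CDKN1A 0.052 ± 0.26, ATF4 0.022 ± 0.27, ACTB -0.095 ± 0.20 and GAPDH 0.10 ± 0.21, none past the threshold. MKI67 had 9 counts after tRF-SC and 1 after tRF-HIS, a ratio of 6.69 (0.927 to 293). DICER1, at 0 after tRF-SC, was at least 3.59-fold higher after tRF-HIS by counts in 1 of its 2 libraries (adjusted p = 0.356).

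In polysome RNA, 1230 genes had an unadjusted p under 0.05 in edgeR's test, where 507 would be expected by chance. In simulated data of this fit, however, 11.19% of unchanged genes had such a p. The 1230 genes are therefore no measure of an effect of tRF-HIS. DESeq2 called 25 genes higher and 24 lower. The count of called genes was 0 in a fit to the polysome libraries alone, in voom with a spread per group and without tRF-SC replicate 2, and it was 6, 4 and 15 without tRF-SC replicate 1, tRF-HIS replicate 1 and tRF-HIS replicate 2.

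The third comparison asked which mRNAs were depleted from or enriched in polysomes, over both transfections. The largest coherent groups were mRNAs of the translation machinery, which were lower in polysome than in input RNA at camera's preset correlation. With an estimated correlation, the ribosomal protein and TOP lists missed the threshold (adjusted p = 0.0542 for each). Of the large ribosomal subunit protein mRNAs, 46 of 47 fell (46 adjusted over the list alone), with a median log2 fold change of -1.09, and of the small subunit ones 30 of 33 fell (31 adjusted over the list alone), with a median of -1.18. RPS12 averaged 1364 ± 290 CPM in input and 257 ± 67.7 CPM in polysome RNA (mean ± SD, n = 4 each), and RPLP0 averaged 6750 ± 454 and 2230 ± 191 CPM. Of the other mRNAs with a terminal oligopyrimidine (TOP) start, 15 of 25 fell (20 adjusted over the list alone), with a median of -1.43. PABPC1, the cytoplasmic poly(A)-binding protein, fell by 2.92 ± 0.17 on the log2 scale, from 2475 ± 316 to 328 ± 21.3 CPM.

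Within these lists, RPS29 had a log2 fold change of -2.25 ± 0.19, RPL41 -1.91 ± 0.17, RPLP1 -1.76 ± 0.15, RPS18 -1.76 ± 0.16, RPL10 -1.71 ± 0.16 and RPS16 -1.56 ± 0.16, and that of RPS12 was -2.42 ± 0.21 and that of RPLP0 -1.60 ± 0.14. TPT1 had -2.62 ± 0.18, the elongation factor EEF1A1 -1.73 ± 0.16 and EEF1G -1.57 ± 0.15, and the value of EEF1G was -1.55 ± 0.15 when summed with its 2 sequence copies. The adjusted p of the 12 genes named so far in this comparison was at most 2.9e-07.

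Mitochondrially encoded mRNAs, which are translated inside mitochondria, were also lower in polysome RNA, though not past the threshold with an estimated correlation (adjusted p = 0.0542). Of the 12 measured, 10 fell (10 adjusted over the list alone), with a median of -2.61. MT-ND1 had a log2 fold change of -4.00 ± 0.27, from 639 ± 149 to 41.5 ± 17.7 CPM, MT-ATP6 -3.61 ± 0.27, MT-CO2 -3.55 ± 0.21 and MT-CO3 -2.68 ± 0.20. Noncoding hosts of small nucleolar RNAs and other substrates of nonsense-mediated decay were lower as well, with 9 of 18 members that fell (12 adjusted over the list alone) and a median of -1.52 (adjusted p = 0.0542 with an estimated correlation). SNHG5 had -2.82 ± 0.40, SNHG29 -2.41 ± 0.21, GAS5 -2.35 ± 0.24 and ZFAS1 -2.09 ± 0.26. GAS5, SNHG1, SNHG5, SNHG6 and SNHG8 belong to both this list and the TOP list. Among nuclear long noncoding RNAs, 2 of 8 fell (4 adjusted over the list alone), with a median of -1.59 (adjusted p = 0.0838 with an estimated correlation). NEAT1 had -2.06 ± 0.43 and PVT1 -2.33 ± 0.49. MALAT1, at -1.85 ± 0.56 (adjusted p = 0.0665), and OIP5-AS1, at -1.72 ± 0.58 (adjusted p = 0.107), did not pass. The tRF-HIS polysome libraries held 0 and 15 counts of MALAT1, whose value ran from -6.17 to -1.36 without single libraries.

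mRNAs of the nuclear-encoded respiratory chain had a median log2 fold change of 0.13 between polysome and input RNA, with 37 of 68 members above 0. The median over all genes was -0.16. In fry, which tests a list by itself, the respiratory chain list did not pass (adjusted p = 0.528). Camera, which ranks a list against the other genes, placed it slightly higher than those (adjusted p = 0.0239). With an estimated correlation the adjusted p was 0.819, and the list also did not pass without tRF-SC input replicate 1 or without tRF-HIS input replicate 1. NDUFC2, a subunit of complex I, was the 1 member that rose over all genes and also adjusted over the list alone, from 90.3 ± 10.4 to 204 ± 87.6 CPM (log2 fold change 1.14 ± 0.27, adjusted p = 0.0154), but it did not pass in 4 of the 8 fits without 1 library. NDUFB10 at 0.63 ± 0.21, ATP5F1D at 0.65 ± 0.21 and ATP5MG at -0.60 ± 0.20 did not pass.

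**Figure D3:**
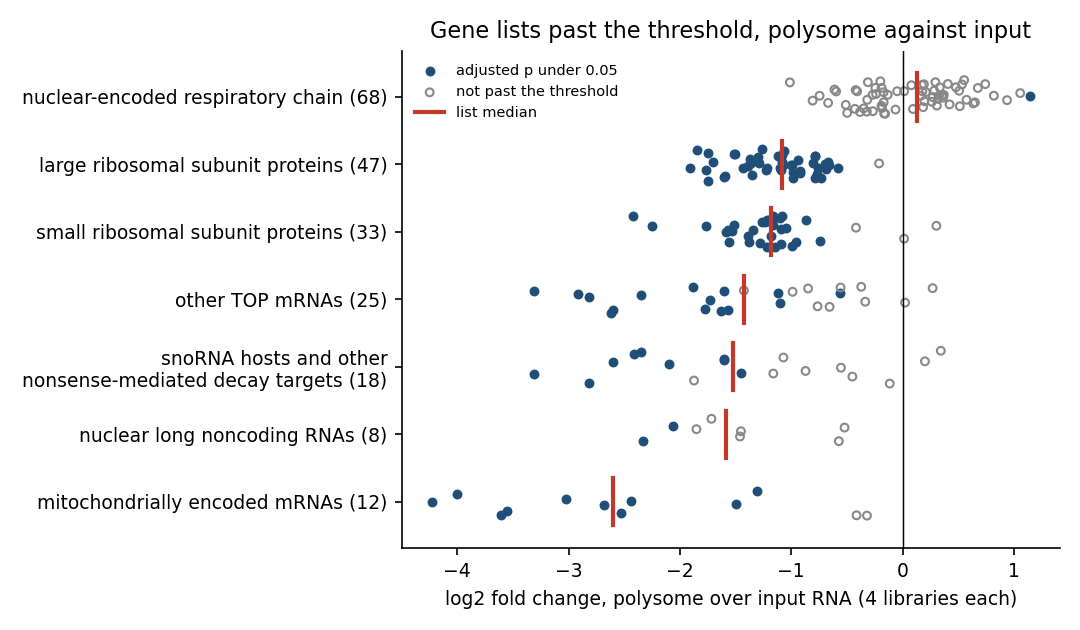
Log2 fold change between polysome and input RNA of each measured member of the 7 lists past the threshold (filled points passed over all genes, open points did not, red bars are list medians, numbers of members in parentheses). Of the large ribosomal subunit protein mRNAs, 46 of 47 fell, while the respiratory chain list centres on a median of 0.13.

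In camera with a preset correlation, the adjusted p was 8.6e-58 for the large and 4.31e-49 for the small subunit proteins, 2.57e-38 for mitochondrial mRNAs, 1.81e-29 for the other TOP mRNAs and 2.01e-14 for the decay substrates. It was 0.000318 for nuclear long noncoding RNAs. With an estimated inter-gene correlation no list passed.

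Across all genes, edgeR's test called 97 genes higher and 276 lower in polysome RNA, of which 86 and 203 are annotated as protein-coding. Scaling moved this split. Library totals gave 391 higher and 214 lower, median-ratio size factors 150 and 246, and DESeq2 306 and 333, and the median log2 fold change of all genes moved by 0.257 between TMM and library totals. Of the 80 ribosomal protein mRNAs, 76 were called lower with TMM and 64 with library totals, with medians of -1.15 and -0.89. The count of 373 called genes also moved when single libraries were left out. Those fits filtered the genes anew and tested 8961 to 12387 genes, against 10131 with all libraries.

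The genes with the largest rises were mostly modest in expression. DBP, a circadian transcription factor, averaged 92.8 ± 22.3 CPM in input and 236 ± 80.8 CPM in polysome RNA, a log2 fold change of 1.35 ± 0.27 (adjusted p = 0.0029). MED18, a subunit of the Mediator complex, had 1.72 ± 0.35 (adjusted p = 0.0039), AARD 1.37 ± 0.29, NSMCE3, a subunit of the SMC5/6 complex, 1.64 ± 0.44, and SFT2D3 1.62 ± 0.37. C2CD4D had 2.29 ± 0.61 and the noncoding LINC02875 1.92 ± 0.44. In the 8 fits without 1 library, the call was lost in 6 for C2CD4D and NSMCE3, in 4 for SFT2D3 and PWP2, in 3 for LINC02875, in 2 for MED18 and LGALS7B and in 1 for AARD. LGALS7B had 1.36 ± 0.30 alone and 1.32 ± 0.29 summed with its copy LGALS7, and both passed. PTP4A1 had 4.17 ± 0.51 alone but 0.10 ± 0.32 summed with ENSG00000285976, and PWP2 had 3.62 ± 0.88 alone but -0.71 ± 0.42 summed with ENSG00000275464, so neither rise held once the shared sequence was counted together.

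The 10 largest falls were genes at 0 in all 4 polysome libraries, for which a floor of 3 counts over these libraries gives a lower bound. 7SK, a nuclear noncoding RNA that restrains transcription elongation, averaged 445 ± 143 CPM in input RNA and was at least 251-fold lower in polysome RNA. Summed with the 7 genes that share its sequence, it had a log2 fold change of -7.20 ± 0.36. How far the noncoding RNAs of this paragraph passed the poly(A) selection in each fraction was not tested. Unnamed genes resembling ribosomal RNA took 6.58 to 10.1% of counts in input libraries and 3.20 to 4.50% in polysome libraries. RNVU1-7, a variant of the U1 small nuclear RNA, was at least 16.9-fold lower alone and had -3.30 ± 0.60 summed. RN7SL3, of the signal recognition particle RNA family, was at least 15.1-fold lower, the antisense transcripts TMEM44-AS1 and STARD7-AS1 at least 9.50-fold and 8.38-fold, RN7SKP203 at least 8.13-fold and the amino acid transporter gene SLC7A6 at least 7.23-fold. Without 1 library, the call of RNVU1-7 was lost in 5 of 8 fits and that of RN7SKP203 in 3 of 7. PEDS1-UBE2V1, NME1-NME2 and UPK3BL2 were at least 35.1-fold, 18.5-fold and 13.7-fold lower alone. Summed with the genes of shared sequence they had -0.23 ± 0.18, -0.31 ± 0.15 and 0.000698 ± 0.35, and none of the 3 passed. Of all called genes, 8 of the 97 higher and 47 of the 276 lower ones shared at least 50% of their 50-nt words with other genes, and 3 and 32 of these passed in the same direction when summed.

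MKI67 was lower in polysome RNA, at 26.3 ± 3.39 CPM in input and 4.92 ± 5.26 CPM in polysome RNA (log2 fold change -2.87 ± 0.77, adjusted p = 0.0346). It rested on 10 polysome counts and was lost in 4 of the 8 fits without 1 library. ATF4, a transcription factor of the integrated stress response, was lower too, at 642 ± 59.4 and 352 ± 30.7 CPM (-0.86 ± 0.19, adjusted p = 0.0064). QTRT1 had -1.10 ± 0.43 (adjusted p = 0.160), QTRT2 -0.44 ± 0.82, HARS2 0.26 ± 0.37, CCND1 -0.37 ± 0.20, MYC -0.34 ± 0.27, CDKN1A 0.28 ± 0.18 and ACTB 0.12 ± 0.14, and none of these passed. DICER1 had 7 polysome counts, all in 1 library, and averaged 11.1 ± 4.29 CPM in input and 5.54 ± 11.1 CPM in polysome RNA (adjusted p = 0.233). HARS1 had -0.18 ± 0.28, GAPDH -0.09 ± 0.15 and ESR1 -0.20 ± 0.52, and these 3 values turned positive with library totals.

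The last comparison asked whether the polysome-to-input ratio of any mRNA differed between tRF-HIS and tRF-SC, in a single model over both kinds of library. No gene passed (0 of 10131 in edgeR's test, smallest adjusted p = 0.582), with 594 genes at an unadjusted p under 0.05, and DESeq2 called 1 gene higher and 1 lower. MT-RNR1, the small mitochondrial ribosomal RNA, was among the genes with the smallest p, with a difference of -1.69 ± 0.41 in log2 ratio (adjusted p = 0.625). In polysome RNA it measured 258 ± 36.4 CPM after tRF-SC and 99.6 ± 60.6 CPM after tRF-HIS, and in input RNA 4496 ± 831 and 5455 ± 837 CPM (mean ± SD, n = 2 each). S100A8 had a difference of -3.35 ± 0.84 (adjusted p = 0.625) and HAUS4 one of 3.60 ± 0.96 (adjusted p = 0.710). ADCY9, GAS8, RBM14-RBM4 and RPL17P7, whose polysome counts were 1 to 3 or 0 in a group as given above, had adjusted p values from 0.582 to 0.784.

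UQCC6, an assembly factor of respiratory complex III, was listed at 0 in both tRF-HIS polysome libraries, at least 11.4-fold below tRF-SC, with input levels of 12.7 ± 1.63 CPM after tRF-SC and 14.7 ± 0.492 CPM after tRF-HIS. PXN-AS1 and RPL41P2 were at 0 in both tRF-SC polysome libraries and at least 8.20-fold and 9.63-fold higher after tRF-HIS, and RPL41P2 had a difference of 0.15 ± 0.34 when summed with RPL41. The adjusted p of these 3 genes alone was 0.625. U2AF1L5 had a difference of -2.54 ± 0.58 alone (adjusted p = 0.625) and -0.22 ± 0.41 summed with U2AF1. ESR1 had 1.66 ± 1.05, QTRT1 -0.88 ± 0.86, QTRT2 -0.53 ± 1.65, HARS1 -0.27 ± 0.55, HARS2 0.20 ± 0.75, MYC -0.24 ± 0.55, CCND1 -0.11 ± 0.39, CDKN1A 0.07 ± 0.36, ATF4 0.17 ± 0.37, ACTB -0.16 ± 0.29 and GAPDH 0.21 ± 0.29, with adjusted p values from 0.877 to 1. MKI67 and DICER1 rested on the few polysome counts given above (adjusted p = 0.889 and 0.848).

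None of the 28 gene lists passed in this comparison with all 8 libraries. Mitochondrially encoded mRNAs had the smallest adjusted p, with a median of -0.73 over 12 members (adjusted p = 0.200; p = 0.385 with an estimated correlation). That list passed as lower in 4 of the 8 fits without 1 library, namely without tRF-SC input replicate 2 (adjusted p = 5.62e-07), tRF-HIS input replicate 1 (0.0396), tRF-HIS input replicate 2 (0.025) or tRF-HIS polysome replicate 2 (0.0039). The estrogen response list had a median of 0.30 with 26 of 36 members above 0 (adjusted p = 0.209). In simulated data of this design, 8.1% of genes with a 16-fold difference were recovered and 0% of those with a 4-fold difference in this fit, and no other fit was simulated for this comparison. Without a single library the number of called genes was 1 to 4 in 3 cases, namely 1 without tRF-HIS input replicate 2, 4 without tRF-SC polysome replicate 1 and 3 without tRF-HIS polysome replicate 1.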

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

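The GC correction, the block with a GC correction, voom with a spread per group, the summed counts of genes with shared sequence and the interferon list without tRF-HIS replicate 2 in both fractions were chosen after the data were seen. The other settings were planned. Of 829 alternative values for named genes, and the interferon list median, past the threshold, 755 kept direction and call, 71 lost the call and 3 turned. Of 1432 values for named genes not past it, 1316 kept both, 49 came to pass and 67 turned. In each comparison without a library, its partner is assumed to vary like the other groups. Depth was lower in the polysome libraries, where 3 counts equalled 5.56 to 10.6 CPM, against 0.542 to 1.37 CPM in input RNA. At equal depth, polysome replicates still correlated at 0.828 and 0.796, against 0.894 and 0.906 in input RNA. How much each of depth and spread limited the polysome comparisons was not tested.

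In input RNA, the count of genes was 0 in most settings, including each left-out library (0 to 0), but 4 with only the compared libraries and 4 in voom. Both settings keep a separate spread for input libraries. In polysome RNA, where 1 gene passed, the count was 0 with library totals, with only the compared libraries and in voom, 3 with a filter of 1 CPM in 4 libraries, 25 with no filter and 49 in DESeq2. It was 0 to 15 without single libraries. Polysome against input RNA gave 605 genes with library totals, 639 in DESeq2 and 174 to 627 without single libraries. The difference between transfections gave 2 genes with no filter, 2 in DESeq2 and 0 to 4 without single libraries. Fits with fewer libraries filtered the genes anew. They tested 8961 to 8981 genes without an input library and 12354 to 12387 without a polysome library. With only the compared libraries, 11792 genes were tested in input RNA and 5512 in polysome RNA. How far the changed gene sets moved the counts was not tested, nor was any other cause of these shifts.

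The number of lists in input RNA was 1, but 0 with an estimated correlation, 0 in fry, 2 with the GC correction and 3 to 9 without single libraries. Ribosomal protein lists were lower without tRF-SC replicate 1 or tRF-HIS replicate 2 and higher without the other 2. Polysome RNA gave 0 lists, but 1 with the GC correction (mitochondrial mRNAs, lower) and 0 to 1 without single libraries. In fry, 0 lists passed with a direction, but 6 passed its mixed test, which asks for changes either way (estrogen response, G2 and M phase, p53 targets, stress response, spliceosome and ribosome biogenesis). Polysome against input RNA gave 7 lists, 6 to 9 without single libraries and 0 with an estimated correlation, while fry passed 9 with a direction and 24 in its mixed test. The difference gave 0 lists and 0 to 4 without single libraries, where mitochondrial mRNAs passed as lower in 4 of the 8 fits. For these lists the cause was not tested.

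Replicate numbers did not clearly pair the samples by the check on deviations from the group means. The r was 0.338 between the input groups, 0.0605 and 0.0615 between fractions and -0.0038 between the polysome groups. However, the slope on GC content was lower in replicate 2 than in replicate 1 of every group. In polysome RNA it was 0.1044 and -0.0032 in tRF-SC replicates 1 and 2, and 0.0455 and -0.1466 in the tRF-HIS ones. With a block, the counts of genes were 0, 3, 486 and 2 in the 4 comparisons in the order of the report. The counts of lists were 1, 1, 9 and 0. The block was the replicate number in the first 2 comparisons and the transfection with the replicate number in the last 2. The block with the GC correction gave 0, 0, 482 and 4 genes and 2, 1, 9 and 1 lists.

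Values that turned were mostly near 0, and the cause was not tested unless stated. Ranges of log2 fold change without single libraries in input RNA were -0.0806 to 0.26 for ACTB, -0.0019 to 1.01 for DICER1, -0.14 to 0.0448 for CCND1, -0.16 to 0.0045 for GAPDH, -0.0643 to 0.0984 for CDKN1A, -0.23 to 0.0146 for ATF4, -0.28 to 0.0996 for MKI67, -0.18 to 1.92 for IFI27 and -0.0316 to 0.18 for QTRT1. The interferon list median ran from -0.0038, without tRF-HIS replicate 2 in both fractions, to 0.65. In polysome RNA the ranges were -0.28 to 0.0997 for ACTB, -0.50 to 0.0397 for CCND1, -0.10 to 0.33 for GAPDH, -0.86 to 0.49 for HARS2, -0.0764 to 0.16 for CDKN1A, -0.13 to 0.14 for ATF4, -0.71 to 0.47 for MYC, -7.19 to 1.02 for QTRT2 and -0.48 to 0.13 for HARS1. Between polysome and input RNA they were -0.0221 to 0.17 for ACTB, -4.19 to 0.19 for ESR1, -0.19 to 0.49 for HARS2 and -3.97 to 0.0524 for QTRT2. For the difference between transfections they were -0.34 to 0.0334 for ACTB, -0.54 to 7.98 for DICER1, -0.42 to 0.12 for CCND1, -0.61 to 0.74 for HARS2, -0.061 to 0.17 for CDKN1A, -0.94 to 0.25 for MYC, -7.46 to 0.75 for QTRT2 and -0.61 to 0.0026 for HARS1.

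In input RNA, CDKN1A turned to 0.0048 with median-ratio size factors, 0.0273 with library totals, 0.0393 with no filter, 0.0056 in DESeq2, 0.0075 with only the compared libraries, 0.0018 in voom, 0.0911 with the GC correction and 0.0914 with block and GC correction. GAPDH turned to 0.0245 with the GC correction and 0.0198 with block and GC correction. In polysome RNA, MYC turned to 0.0047 with median-ratio size factors, 0.0323 with library totals, 0.0046 in DESeq2, 0.0322 with only the compared libraries, 0.0572 with the GC correction and 0.0444 with block and GC correction, and HARS2 to 0.0036 with only the compared libraries. Between polysome and input RNA, library totals, which raise all values, turned ESR1 to 0.0509, GAPDH to 0.17 and HARS1 to 0.0821. Summing with genes of shared sequence turned PWP2 to -0.0178 in input RNA and to -0.71 between polysome and input RNA, RPL36A-HNRNPH2 to 0.10 in input RNA and UPK3BL2 to 0.000698 between polysome and input RNA.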

Other observations

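Tests chosen after their result was seen are those of GC content within groups and of histidine codons, and the GC correction. Members of further lists changed between polysome and input RNA without a call of the list. The iron-storage mRNAs FTL and FTH1 fell by 1.72 ± 0.18 and 1.06 ± 0.15 on the log2 scale (adjusted p = 3.94e-07 and 3.78e-05), and DDIT3, a transcription factor of the integrated stress response, had -1.99 ± 0.49 (adjusted p = 0.0198), while CEBPB of the same list rose by 0.83 ± 0.18 (adjusted p = 0.0054). GREB1, an estrogen-induced gene, had -0.88 ± 0.19 (adjusted p = 0.0079), the replicative polymerase POLE -3.24 ± 0.78 (adjusted p = 0.0171), OST4 of the oligosaccharyltransferase -1.68 ± 0.29 (adjusted p = 0.000546) and YBX1, an RNA-binding protein, -0.99 ± 0.19 (adjusted p = 0.0016). The splicing list held DDX5 at -0.93 ± 0.22, SRSF5 at -1.14 ± 0.30, PRPF3 at -1.78 ± 0.40 and RBM39 at -1.33 ± 0.36, each past the threshold. Among genes that rose were the junction protein CLDN3 (0.68 ± 0.17), JUND (0.80 ± 0.19), the p53 target PHLDA3 (0.80 ± 0.18) and ISG15 (0.85 ± 0.22), and the p53 target PLK2 fell, with -1.33 ± 0.37.

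The median over all genes was -0.16 between polysome and input RNA. Medians of the lists that hold the genes above were -0.072 for heat shock and oxidative stress (adjusted p = 0.863), -0.044 for the integrated stress and unfolded protein response (adjusted p = 0.969), 0.013 for estrogen response (adjusted p = 0.779), -0.32 for S phase (adjusted p = 0.673), -0.23 for G2 and M phase (adjusted p = 0.863), 0.11 for G1 regulators (adjusted p = 0.374) and -0.21 for the interferon response (adjusted p = 0.863). The secretory translocon had -0.21 (adjusted p = 0.863), tRNA fragment biogenesis and Argonaute -0.24 (adjusted p = 0.863), spliceosome -0.14 (adjusted p = 0.863), luminal markers 0.11 (adjusted p = 0.0540) and p53 targets -0.16 (adjusted p = 0.674). Lists with no member past the threshold were the cytosolic tRNA synthetases at -0.29 (adjusted p = 0.288), the queuosine pathway at -0.44 (adjusted p = 0.863), basal markers at -0.83 (adjusted p = 0.323), cholesterol synthesis at -0.034 (adjusted p = 0.674), hypoxia and glycolysis at 0.10 (adjusted p = 0.268), NF-kB at -0.28 (adjusted p = 0.817), proteasome at 0.12 (adjusted p = 0.107), histones at -0.50 (adjusted p = 0.993) and ribosome biogenesis at -0.25 (adjusted p = 0.993). Fibroblast and blood markers had 4 and 1 tested members and were not tested as lists.

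Fold changes between tRF-HIS and tRF-SC input RNA fell with GC content (rho -0.45). The same relation within groups was stronger, with a rho of -0.67 between the tRF-SC replicates, so a recovery by GC content that differs from library to library may account for it. The slopes of the groups interleaved, with the higher tRF-HIS slope at 0.0259 log2 CPM per 10 points of GC and the lower tRF-SC slope at -0.148. Such interleaving had been set in advance as evidence against an effect of the fragment, but the overlap of 0.17 was smaller than the differences between replicates (0.49 and 0.25), so that bound was wrong for slopes that vary by library. An effect of the fragment, with tRF-HIS minus tRF-SC rho values of -0.53 in replicate 1 and -0.15 in replicate 2, stays open and cannot be told apart from differences between libraries with 2 per group.

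The interferon list was higher in tRF-HIS input RNA with a median of 0.32, a call that was lost with an estimated correlation (camera, adjusted p = 0.834). A recovery by GC content did not account for it, since the median was 0.2937 after the GC correction and the list still passed at the preset correlation. A single library may account for it, because the adjusted p was 0.9127 without tRF-HIS replicate 2. An effect of the fragment stays open and cannot be told apart from that library, since the lower tRF-HIS input library had a list mean of 4.9703 log2 CPM, just above both tRF-SC libraries, while in polysome RNA the groups overlapped. Another tRF-HIS culture would separate these.

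Ribosomal protein mRNAs were lower in polysome than in input RNA, with a median of -1.15 over 80 genes. Of 10000 lists drawn from genes similar in coding length, expression and GC content, 0 had a median as low. The lowest was -0.081. The lists drew on 203 distinct genes, the 20 nearest of each ribosomal protein gene. They therefore overlap, and 0 of 10000 is not a p-value. The drawn genes were also somewhat less expressed (9.59 against 10.4 median log2 CPM). The scaling between fractions does not account for it, as the median was at most -0.8926 under the other scalings. A difference in ribosome load and one in recovery between the fractions were not tested, and both stay open.

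Of the 35 ways to split the 8 libraries 4 against 4, 1 gave as many genes as the real split of polysome against input RNA, namely the real split itself, with 399 genes in a fit of 2 groups. The highest other split gave 2 genes. The other splits hold polysome and input libraries on both sides, which widens their spread. Their low counts therefore do not estimate false calls and cannot decide whether a chance split would call as many genes.

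A further hypothesis was that tRF-HIS changes the ribosome association of mRNAs rich in histidine codons. Across 9346 genes the share of histidine codons had a Spearman rho of 0.000186 with the difference between transfections in the log2 polysome-to-input ratio, so no such relation was seen. The share of codons read by queuosine-modified tRNAs had a rho of -0.034 with the same difference. Its relation with the fold change in input RNA was the strongest of the 8 codon relations examined (rho 0.29) and was not separated from GC content. Genes are not independent replicates in these relations.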
